A study of Mus musculus with 6 samples.

How the data were processed

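Gene expression was measured in mouse hematopoietic stem cells (HSCs), the cells from which all blood lineages arise, on 6 Affymetrix arrays of biotin-labelled cRNA made from total RNA. Per the labels, 3 arrays held fetal liver HSCs from embryonic day 14.5 and 3 arrays held bone marrow HSCs from male C57BL/6 mice of 25 months, here called old HSCs. The fetal liver cells were also C57BL/6, and their sex was not given in the sources used here. Per the design text, both sorts kept lineage-negative cells with c-Kit and Sca1 on their surface. The fetal liver gate further asked for CD150 and Mac1 without CD48, and the old gate for cells without CD34 and Flk2. Tissue, age and gate therefore changed together between the groups, and the labels did not show whether sex or array batch did. Xist, given below, points to a possible difference in sex composition, while the Y-linked transcripts tested were not lower in fetal liver. A group of young adult mice named in the design text was not analysed here, and 4 columns of the whole-series table that belonged to no sample listed for the series were not used.

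The deposited values were probe set intensities on a linear scale, which the authors had made with GCRMA, a background correction, normalization and summary for such arrays, per the submitters' processing notes. The GCRMA version was not given in the sources used here. The lowest intensity was 4.71981 on every array (2.24 on the log2 scale) and was shared by many probe sets, so a probe set at this floor had no measured level. The series value table was used, and the same 6 columns of the whole-series table differed from it by at most 0. No further normalization was applied. The number of arrays, 3 per group, limited the precision.

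Values were log2-transformed. Of 45101 probe sets, 64 were array controls and were left out, and 19859 exceeded 4 on the log2 scale (an intensity of 16) in at least 3 of the 6 arrays and were tested, which left 25178 untested. Gene names came from the platform annotation. It gave 1 symbol for 34958 probe sets, several for 932 and none for 9211. A table of RefSeq genes matched 34754 of them and changed 0 symbols. Each gene was represented by the tested probe set, among those naming exactly 1 gene, with the highest mean over the 6 arrays, giving 9907 genes. Of these, 4313 had several tested probe sets, and in 409 genes probe sets passed the threshold in opposite directions.

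Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 change is old minus fetal liver, and "rose" and "fell" refer to old HSCs against fetal liver HSCs among genes past the threshold. Where a group had arrays at or below 4, the fold is given as "at least", computed from group means after values below 4 were set to 4. The 33 gene lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, over the 31 lists with at least 3 tested members. Camera compares a list with the other genes. Fry tests whether a list's genes move, on balance, in a common direction, or, in its mixed form, whether they change in either direction, and compares them with no other genes. Families of genes with a shared symbol stem and at least 10 tested members (116 families) were tested in the same way. List medians are given relative to the median log2 change of all tested genes, which was -0.24.

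The groups, the tests, the filter, the 33 lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with separate groups, leaving out provisional symbols. It also names up to 4 called members of each list with the largest change and, where few were called, up to 2 others, up to 3 called members of a symbol family past the threshold, and a fixed set of HSC, DNA methylation, Polycomb and sex-linked genes. Of that set, Itgam, Tet3, Sox17 and Lin28b did not exceed 4 in 3 arrays and were not tested, while Ly6a and Ddx3y were not named by the annotation and were not analysed here. Further genes named to account for a count of 5 or fewer, and the globin probe sets, were chosen after their values were seen. These genes were Rfc3, Impact, Ndn, Btg2, Birc3, Ppbp, Car1, Aqp1, C1qb, Csf1r, Fcgr3, Cd68, Adgre1, Prtn3, Csf3r, Padi4, Pdk1, Cbx7, Etv6, Gfi1b, Zfx, Mecom, Hlf, Emcn, Tek, Egfl7, Col1a2, Cdkn1a, Ndufa2, Nop2, Calr and Bag3.

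The test was checked on simulated arrays, in which each gene had 1 pooled SD for both groups and 200 of 9907 genes had been changed. At a log2 change of 1, 27 of 100 changed genes were recovered, and at a log2 change of 2, 71 of 100, with 0 false calls. The real groups differed in spread (median SD of a gene 0.148 in fetal liver and 0.344 in old arrays), and 5166 genes were called. The simulation therefore does not cover unequal spread, and its shares need not hold for these data. RNA quality was read from the log2 signal of the 3′ minus the 5′ control probe sets for Gapdh and actin, and compared by an exact permutation test, whose smallest two-sided p with 3 against 3 arrays is 0.1. Alternatives were no filter, a filter at 6, quantile normalization, centring on the median or on the percentile 75, limma without the trend or with its robust option, a replicate block, each array left out in turn, other thresholds, probe sets without possible cross-hybridization, and the mean of a gene's probe sets. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Figures were drawn with matplotlib 3.10.9.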

Results

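HSCs from fetal liver at E14.5 (3 arrays) were compared with HSCs from the bone marrow of mice aged 25 months (3 arrays). The series title places the work in a study of DNA methylation, proliferation and HSC ageing, and this comparison addresses which genes differ between stem cells of the fetal liver and those of old marrow. Between 41.8% and 43.0% of the probe sets exceeded 4 on the log2 scale on each array, and between 33.3% and 37.2% lay at the floor. The fetal liver arrays correlated with each other at 0.989 to 0.991 across probe sets, and old replicates 1 and 2 at 0.987. Old replicate 3 stood somewhat apart, at 0.954 and 0.941 with the other old arrays. Between groups the correlations were 0.799 to 0.823. Genes and probe sets are not independent replicates, and these correlations are descriptions of the arrays.

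Old HSCs differed from fetal liver HSCs across much of the transcriptome measured. Genes of cell division, DNA replication, DNA methylation and the fetal HSC programme were lower in old HSCs, while genes of antigen presentation, the interferon response, the immediate early response, platelets and HSC ageing were higher. With an estimated correlation the mitosis and HSC ageing lists kept their calls, and the lists of the other genes just named had adjusted p-values of 0.135 to 0.166, while 12 of 15 erythroid and 13 of 17 granulocyte and monocyte markers fell in the same arrays. Of 9907 genes tested, 5166 (52.1%) passed an adjusted p of 0.05, of which 1899 rose and 3267 fell. An absolute log2 change of at least 1 was reached by 1297 of the risen and 2061 of the fallen genes. In 6061 genes (61.2%) the groups did not overlap, where chance gives 10% for 3 against 3 arrays. The split between rises and falls moved with the scaling, since 2404 rose and 2641 fell after the arrays were centred on their percentile 75. The number of called genes rose to 7025 without old replicate 3.

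**Figure D1:**
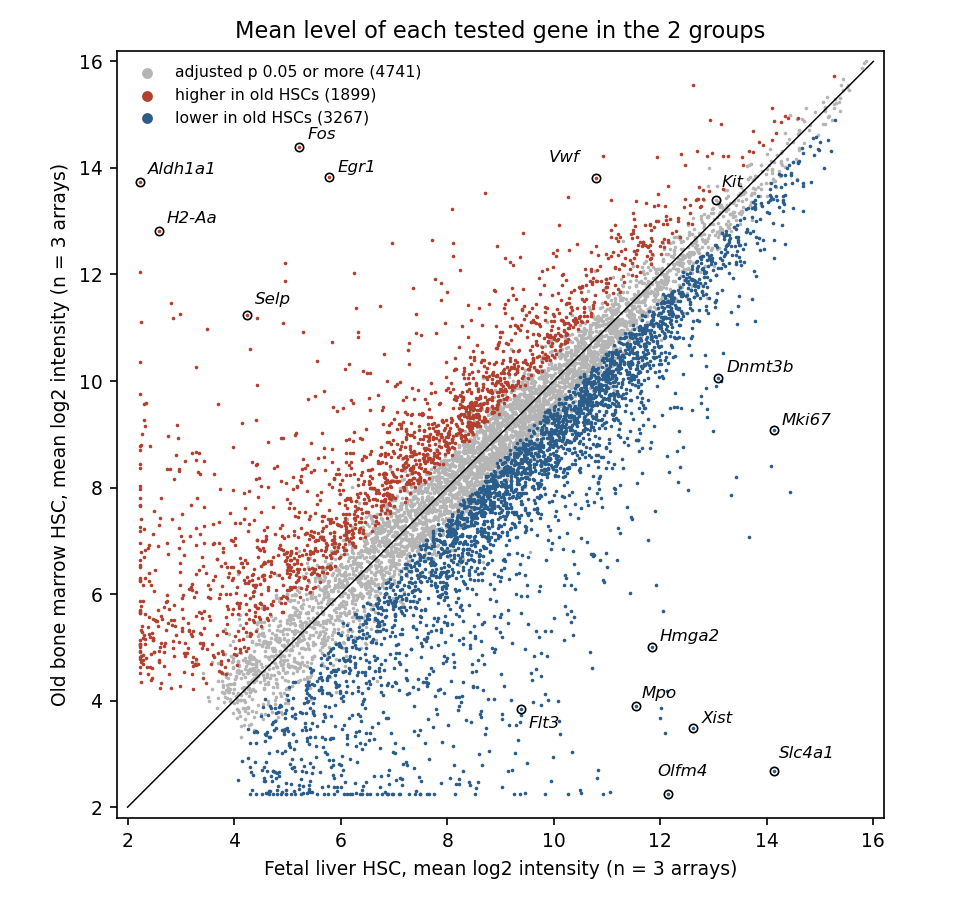
Mean log2 intensity of each of the 9907 tested genes in fetal liver HSCs (x axis, 3 arrays) and old HSCs (y axis, 3 arrays), with the line of equal levels. Red points are the 1899 genes that rose in old HSCs, blue points the 3267 that fell and grey points the others, and circled genes are named in the text.

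The largest rise by log2 change, with floor values taken as they stand, was in Aldh1a1. This gene encodes an enzyme that oxidises retinal to retinoic acid and serves as a stem cell marker. Its log2 intensity was 13.74 ± 0.28 (SD, n = 3) in old HSCs and at the floor on all 3 fetal liver arrays, so it was at least 855-fold higher (adjusted p = 3.32e-07). H2-Aa, a chain of major histocompatibility complex (MHC) class II, was at least 453-fold higher, Sbspon at least 265-fold, Nupr1, a stress-induced chromatin protein, at least 176-fold, and Galnt6, which starts O-linked glycosylation, at least 154-fold. Rgs1, a regulator of G protein signalling, was at least 145-fold higher, the sulfotransferase Sult1a1 at least 138-fold and the lectin receptor Clec1a at least 81.7-fold. Fos and Egr1, transcription factors of the immediate early response, were measured in both groups and were 580-fold and 264-fold higher.

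The largest fall was in Slc4a1, the anion exchanger of the red cell membrane, from 14.14 ± 0.32 (SD, n = 3) in fetal liver HSCs to 2.68 ± 0.40 in old HSCs (adjusted p = 3.75e-07), at least 1125-fold lower. Further red cell membrane genes among the 10 largest falls were Ermap (at least 199.7-fold lower, with 1 of 3 old arrays above 4), Rhd (at least 133-fold), Rhag (at least 91.3-fold) and Epb42 (at least 90.6-fold). Neutrophil genes were also among them, with Olfm4 at least 282-fold lower, Ltf, which encodes lactoferrin, at least 270-fold (1 of 3 old arrays above 4), and Stfa3 at least 121-fold. Xist, the RNA that silences an X chromosome in female cells, was at least 394-fold lower, and Ddx4, an RNA helicase of germ cells, at least 112.5-fold. By the rule that chose these 20 genes, all 3 old arrays of each lay on the same side of all 3 fetal liver arrays. Their ranks rest on log2 changes that take values near the floor as they stand. The bounds of Ddx4, Rhag and Epb42 lie below the fall of Hmga2 (113.4-fold, above 4 on all arrays), so their place among the 10 is not settled. S100a9 and Mpo, given below and outside the 10, had higher bounds than Rhd and Stfa3, whose places are also not settled. The same limit holds for rises from fetal liver values near the floor.

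Genes of the cell cycle were lower in old HSCs as a block. All 26 tested mitosis genes fell, also when adjusted over the list alone, and the proliferation marker Mki67 was 33.2-fold lower (14.13 ± 0.10 against 9.08 ± 0.24, SD, n = 3; adjusted p = 1.17e-06). Kif20a and Cenpe, a pair of mitotic motor proteins, were at least 41.4-fold and at least 39.1-fold lower, and the ubiquitin-conjugating enzyme Ube2c was 39.0-fold lower. The median change of the mitosis list was -4.14 relative to all genes, or -4.10 with genes near the floor at their bounds (camera adjusted p = 1.52e-14). This was 1 of 2 list calls that held with an estimated correlation (adjusted p = 0.0282); the other was the HSC ageing list. In the same arrays 12 of 15 erythroid markers fell.

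Of 25 DNA replication genes, 24 fell and 0 rose, the same counts as when adjusted over the list alone, with a median of -2.08 relative to all genes (camera adjusted p = 4.52e-09; adjusted p = 0.166 with an estimated correlation). The ribonucleotide reductase subunits Rrm2 and Rrm1, which supply deoxynucleotides, were 37.0-fold and 8.72-fold lower, Mcm10, which acts at replication origins, 22.7-fold and the origin licensing factor Cdc6 16-fold. Rfc3, at -0.51, did not pass. Genes of homologous recombination and the Fanconi pathway, which repair breaks and crosslinks in DNA, fell in 15 of 19 cases (17 adjusted over the list alone) and rose in 0. Brca1 was 15.8-fold lower, Blm 10.7-fold and Exo1 at least 9.17-fold (2 of 3 old arrays above 4). The list median was -1.61 relative to all genes, or -1.29 at the bounds (camera adjusted p = 7.42e-05; adjusted p = 0.104 with an estimated correlation). Among 116 symbol families, 3 past the threshold were lower: Cep, named for centrosomal proteins (24 of 33 fell, 1 rose; camera adjusted p = 0.00660), Kif, the kinesins (14 of 22 fell, 1 rose; adjusted p = 0.00736), and Mcm (9 of 10 fell; adjusted p = 0.00736). Each of the 3 had an adjusted p of 0.985 with an estimated correlation. Examples were Cep55 (-4.64), Kif2c (-5.12) and Mcm2 (-2.22).

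Genes of DNA methylation were lower in old HSCs. Of 13 tested writers, erasers and readers, 11 fell and 0 rose, also when adjusted over the list alone, with a median of -1.16 relative to all genes (camera adjusted p = 0.00296; adjusted p = 0.145 with an estimated correlation). Dnmt3b and Dnmt3a, the de novo DNA methyltransferases, were 8.15-fold and 6.09-fold lower, from 13.09 ± 0.05 to 10.06 ± 0.30 and from 11.40 ± 0.13 to 8.79 ± 0.62 (SD, n = 3). Uhrf1, which brings the maintenance methyltransferase to newly copied DNA, was 6.45-fold lower, and the chromatin remodeller Hells 8.82-fold lower. Tet1 and Tet2, which oxidise methylcytosine, were 6.45-fold and 1.90-fold lower. Dnmt1, the maintenance methyltransferase, fell by 0.56 on the log2 scale (adjusted p = 0.0136), and its change was -0.36 after median centring (adjusted p = 0.0679) and -0.47 without fetal liver replicate 2 (adjusted p = 0.0630). For Tet1 the mean of its probe sets gave -0.91 (adjusted p = 0.145). Of the 13 genes, 8 fell after median centring and 9 after quantile normalization, and 0 rose in either. With the mean of probe sets 8 fell and 1, Zbtb38, rose. Mki67 and 12 of 15 erythroid markers were lower in the same arrays.

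Polycomb genes, which encode repressors that modify histones, went both ways. Of 19 tested, 10 fell and 3 rose, also when adjusted over the list alone, with a median of -0.39 relative to all genes (camera adjusted p = 0.535). After median centring 9 fell and 5 rose, and without fetal liver replicate 3, 6 fell and 2 rose. The histone H3 methyltransferase Ezh2 was 6.64-fold lower (12.25 ± 0.11 against 9.52 ± 0.66, SD, n = 3; adjusted p = 0.000306), and its paralog Ezh1 was 3.80-fold higher (8.31 ± 0.12 against 10.24 ± 0.36; adjusted p = 0.000296). Ring1 was 4.97-fold higher, Cbx7 rose by 1.34 on the log2 scale, and Cbx2 was 4.05-fold lower.

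**Figure D2:**
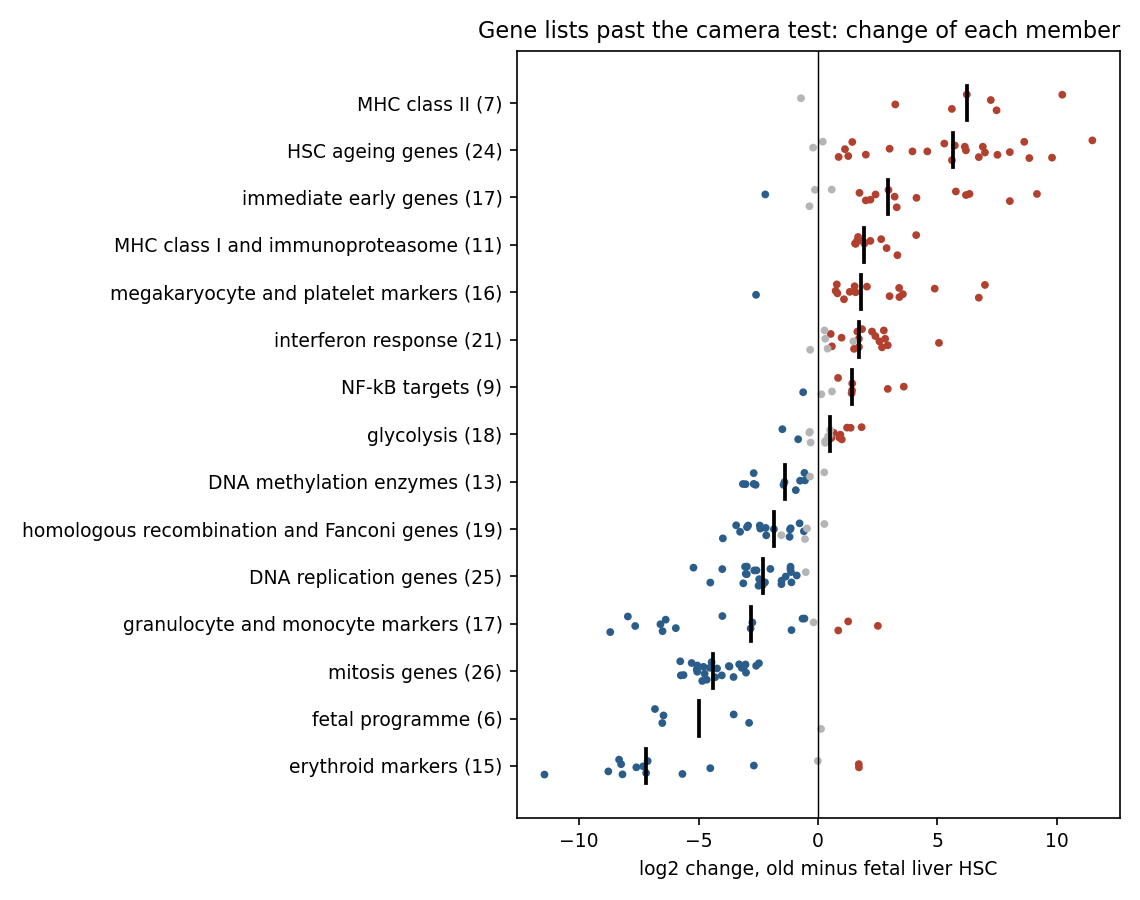
log2 change, old minus fetal liver HSC (x axis), of each tested member of the 15 gene lists past the camera test, with the number of tested members in brackets. Red members rose, blue members fell, grey members did not pass, and black bars mark list medians, from -7.20 for erythroid markers to 6.24 for MHC class II.

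The fetal HSC programme was lower in old HSCs in 5 of its 6 tested members, the same count as when adjusted over the list alone. Of 13 listed genes, 10 were on the array, and Sox17 and Lin28b were among those not tested. Without the filter 6 of 10 fell, and the median log2 change of -5.00 became -2.06. Igf2bp3, Igf2bp1 and Dlk1 exceeded 4 on no old array, so they passed the filter only through fetal liver. The chromatin protein Hmga2 was 113-fold lower (11.84 ± 0.05 against 5.01 ± 0.36, SD, n = 3; adjusted p = 1.17e-06). The RNA-binding proteins Igf2bp3 and Igf2bp1 were at least 37.1-fold and at least 3.40-fold lower, the growth factor Igf2 at least 55.8-fold (1 of 3 old arrays above 4) and Dlk1 at least 2.32-fold. The transcription factor Mycn, at 0.13, did not pass, and it was called higher, at 0.33, after median centring. The list median was -4.76 relative to all genes, or -3.25 at the bounds (camera adjusted p = 0.00326; adjusted p = 0.157 with an estimated correlation). Imprinted genes, expressed from the allele of a given parent, fell in 7 of 11 cases and rose in 3, also when adjusted over the list alone (median -1.53 relative to all genes, or -1.22 at the bounds; camera adjusted p = 0.219). Plagl1 was at least 62.2-fold and Peg3 at least 24.3-fold lower. Impact rose by 1.82, the cyclin-dependent kinase inhibitor Cdkn1c by 0.83 (adjusted p = 0.0209) and Ndn by 0.52 on the log2 scale. The call for Cdkn1c was lost without fetal liver replicate 1, 2 or 3 (adjusted p = 0.0821, 0.0582 and 0.0651), without old replicate 2 (adjusted p = 0.0521) and without the filter (adjusted p = 0.0618). The imprinted median log2 change of -1.77 became -0.28 without the filter (2 risen and 7 fallen of 16) and -0.70 without possibly cross-hybridizing probe sets (3 risen and 4 fallen of 8). The liver proteins Alb and Afp moved with these genes, at least 38.1-fold and 18.6-fold lower in old HSCs.

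Genes often reported as higher in aged than in young adult HSCs were higher in old than in fetal liver HSCs. Of 24 tested, 22 rose and 0 fell, also when adjusted over the list alone, with a median of 5.91 relative to all genes, or 5.04 at the bounds (camera adjusted p = 5.11e-17; adjusted p = 0.0281 with an estimated correlation). P-selectin (Selp) was at least 127-fold higher, with 2 of 3 fetal liver arrays above 4, and von Willebrand factor (Vwf) 8.03-fold higher (10.80 ± 0.17 against 13.81 ± 0.21, SD, n = 3; adjusted p = 7.65e-06). Mt1, at -0.20, and Runx1t1, at 0.21, did not pass. Of these 24 genes, 6 also stood in another list. All 24 exceeded 4 on every old array, but only 14 did so on every fetal liver array. Those at or below 4 on all fetal liver arrays, such as Aldh1a1, passed the filter only through old HSCs. Their rise was nearly set in advance. Young adult HSCs were not analysed here, so ageing cannot be told apart from a difference between adult and fetal HSCs.

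Markers of megakaryocytes and platelets were higher in old HSCs in 15 of 16 cases, also when adjusted over the list alone. The integrin chains Itgb3 and Itga2b, which form the platelet fibrinogen receptor, were at least 106-fold (2 of 3 fetal liver arrays above 4) and 29.7-fold higher, and Gp1bb, part of the receptor for von Willebrand factor, at least 4.15-fold. Ppbp, a platelet chemokine, was at least 2.67-fold lower. The median was 2.05 relative to all genes, or 1.8 at the bounds (camera adjusted p = 4.22e-08; adjusted p = 0.135 with an estimated correlation). Of the 16 genes, 3 also stood in another list. On all old arrays 15 of the 16 exceeded 4, and on all fetal liver arrays 10.

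Genes of antigen presentation were higher in old HSCs. All 11 tested genes of MHC class I and the immunoproteasome, which load peptides for display to T cells, rose, also when adjusted over the list alone (median 2.19 relative to all genes; camera adjusted p = 7.11e-09; adjusted p = 0.145 with an estimated correlation). Nlrc5, the transactivator of class I genes, was 17.4-fold higher, the peptide transporters Tap1 and Tap2 10.1-fold and 7.36-fold, and the proteasome subunit Psmb8 6.29-fold. Of 7 class II genes, 6 rose and 0 fell, with a median of 6.48 relative to all genes, or 5.82 at the bounds (camera adjusted p = 2.71e-05; adjusted p = 0.135 with an estimated correlation). H2-Ab1 was at least 125-fold, H2-Eb1 at least 48.0-fold and the invariant chain Cd74 at least 35.9-fold higher. These genes and H2-Aa exceeded 4 on no fetal liver array and passed the filter only through old HSCs. Their rise was therefore nearly set in advance. H2-Ob, at -0.71, passed as lower when adjusted over the list alone, where 6 rose and 1 fell. Of the monocyte and macrophage markers in the same arrays, Csf1r was at least 12.5-fold lower (1 of 3 old arrays above 4), Fcgr3 at least 3.36-fold lower and C1qb at least 2.64-fold higher, Cd68 fell by 1.10 on the log2 scale, and Adgre1, at -0.18, did not pass. The symbol family H, which holds the MHC genes named H2 and histone genes, was called higher with 11 of 28 members risen and 4 fallen (camera adjusted p = 0.00736; adjusted p = 0.985 with an estimated correlation).

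Interferon response genes rose in 16 of 21 cases (17 adjusted over the list alone) and fell in 0, with a median of 1.95 relative to all genes (camera adjusted p = 4.22e-08; adjusted p = 0.166 with an estimated correlation). The GTPases Iigp1, Igtp and Gbp2, which act against intracellular pathogens, were 33.7-fold, 7.06-fold and 6.79-fold higher, and Usp18 at least 5.21-fold (1 of 3 fetal liver arrays above 4). Of 9 targets of the transcription factor NF-kB, 6 rose and 1, Birc3, fell, also when adjusted over the list alone (median 1.65 relative to all genes; camera adjusted p = 0.00127; adjusted p = 0.135 with an estimated correlation). After quantile normalization and after centring on the median or the percentile 75, and without any 1 fetal liver array or old replicate 1, 6 rose and 0 fell, so the call of Birc3 was lost. Bcl3 was 12.1-fold and Traf1 at least 4.25-fold higher.

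The immediate early genes, which are transcribed within minutes of a stimulus, were higher in old HSCs. Of 17 tested, 13 rose and 1, Btg2, fell, also when adjusted over the list alone (13 rose and 3 fell without old replicate 3). Fos rose from 5.22 ± 0.22 to 14.40 ± 0.30 and Egr1 from 5.78 ± 0.48 to 13.83 ± 0.34 (SD, n = 3). Junb was at least 27.3-fold and Fosb at least 21.8-fold higher. The list median was 3.20 relative to all genes, or 2.93 at the bounds (camera adjusted p = 9.32e-08; adjusted p = 0.166 with an estimated correlation). Regulators of HSC quiescence went both ways, with 9 of 18 risen and 6 fallen (7 fallen adjusted over the list alone; median 0.38 relative to all genes; camera adjusted p = 0.393), and at a filter of 6 the median log2 change was -0.23 against 0.14. Besides Egr1, Nr4a1 was 4.02-fold higher, while the transcriptional repressor Gfi1 was 15.2-fold and the retinoblastoma gene Rb1 3.77-fold lower.

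**Figure D3:**
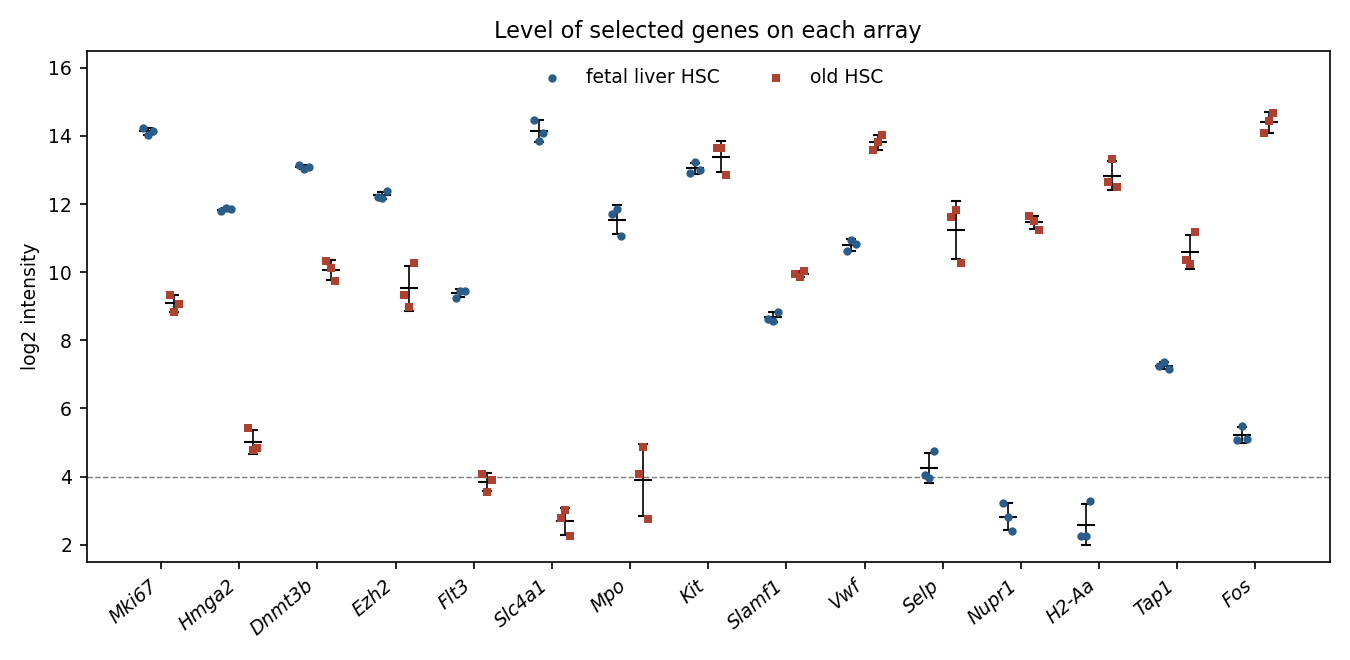
log2 intensity (y axis) of 15 genes on each of the 3 fetal liver (blue circles) and 3 old (red squares) arrays, with black bars for the mean and SD of each group and a dashed line at 4, the level of the filter. Kit lies at 13.05 in fetal liver and 13.39 in old HSCs, while Mki67 and Slc4a1 are lower and Selp and Fos higher on all 3 old arrays.

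Most erythroid, granulocyte and monocyte markers were higher in fetal liver HSCs. Among erythroid markers 12 of 15 fell and 2, Car1 and Aqp1, rose, also when adjusted over the list alone (median -6.96 relative to all genes, or -5.44 at the bounds; camera adjusted p = 1.22e-05; adjusted p = 0.176 with an estimated correlation). A probe set shared by the adult beta-globin genes had a log2 intensity of 15.11 ± 0.10 in fetal liver and 9.24 ± 0.43 in old HSCs (SD, n = 3), and that shared by the alpha-globin genes with the highest mean over the 6 arrays had 14.01 ± 0.15 and 5.63 ± 2.68. Another shared by the alpha-globin genes, brighter in fetal liver, had 14.12 ± 0.22 and 5.19 ± 2.54. The single embryonic globin tested, Hbb-y, was at least 5.61-fold lower in old HSCs (adjusted p = 0.0101, and 0.0777 without the filter). Its probe sets disagreed, since another Hbb-y probe set, not tested, lay at the floor on all 6 arrays. Granulocyte and monocyte markers fell in 13 of 17 cases and rose in 3, also when adjusted over the list alone (median -2.58 relative to all genes, or -1.51 at the bounds; camera adjusted p = 0.000805; adjusted p = 0.325 with an estimated correlation). S100a9 was at least 246-fold lower (2 of 3 old arrays above 4), myeloperoxidase (Mpo) at least 151-fold (2 of 3 old arrays above 4) and Ngp 96.7-fold. The risen members were C1qb, Prtn3 and Csf3r. Above 4 on all fetal liver arrays were 14 of 15 erythroid and 16 of 17 granulocyte and monocyte markers. On all old arrays 5 and 10 were.

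Of 19 hepatocyte markers, 5 were tested, of which 4 fell and 1 rose, also when adjusted over the list alone (median -3.98 relative to all genes; camera adjusted p = 0.0826; adjusted p = 0.289 with an estimated correlation). Transthyretin (Ttr) was at least 23.1-fold lower, and the keratin Krt18 14.4-fold higher. The list passed after centring on the percentile 75 (adjusted p = 0.0485) and without the filter (adjusted p = 0.0147), where 17 were tested, 7 fell and 2 rose, and the median log2 change was -0.64 against -4.22 with the filter. Stromal markers were tested in 5 cases, of which 3 rose and 2 fell, also when adjusted over the list alone (median 1.96 relative to all genes, or 0.73 at the bounds; camera adjusted p = 0.306). Their median log2 change of 1.72 became -3.09 without possibly cross-hybridizing probe sets (1 risen and 2 fallen of 3) and 0.00 without the filter (3 risen and 3 fallen of 15). The proteoglycan Bgn was at least 76.8-fold and Pdgfrb at least 10.7-fold higher, Col1a2 at least 1.41-fold higher, and Postn at least 5.26-fold and Fn1 at least 5.58-fold lower. Endothelial markers rose in 4 of 10 cases and fell in 3, also when adjusted over the list alone (camera adjusted p = 0.435). Cldn5 was at least 23.8-fold (1 of 3 fetal liver arrays above 4), Kdr at least 2.61-fold, Tie1 4.12-fold and Eng 3.86-fold higher, and Emcn, Tek and Egfl7 fell. The endothelial median was -0.10, its mean 0.67 and its test upward, and the median was 0.10 after median centring. Of 24 lymphoid markers 3 were tested and 1, Nkg7, rose (2.66-fold), also when adjusted over the list alone (median 0.83 relative to all genes; camera adjusted p = 0.393), and without the filter 2 rose and 1 fell of 21. The immunoglobulin gene Ighm, not called here, was called higher at a filter of 6 (5.31, adjusted p = 0.000134). It was also called higher with the mean of its probe sets (3.26, adjusted p = 0.000356), where 2 of the 3 lymphoid markers rose. The only tested mast cell marker, Hdc, was at least 9.50-fold lower.

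Among genes of the sorting gates, Kit did not pass at 0.34 (adjusted p = 0.242), and passed at 0.60 without old replicate 3 (adjusted p = 0.00155), and also passed as higher with the mean of its probe sets (adjusted p = 0.00131). A dimmer probe set of Kit was 2.67 higher in old HSCs (adjusted p = 0.000237). Slamf1, which encodes CD150, was 2.42-fold higher in old HSCs. Flt3, which encodes Flk2, was at least 41.0-fold lower (1 of 3 old arrays above 4), Cd48 at least 3.12-fold lower and Cd34 3.74-fold lower (adjusted p = 0.00603; 0.0505 without the filter). The old gate excluded CD34 and Flk2 and the fetal liver gate excluded CD48, so these genes were part of how the cells were chosen. Cd48 was nonetheless the higher in fetal liver HSCs (5.64 ± 0.35 against 2.37 ± 0.12, SD, n = 3), whose gate excluded it, and Slamf1 the higher in old HSCs, whose gate did not ask for CD150. Of 5 gate genes tested 1 rose and 3 fell, also when adjusted over the list alone (median -1.67 relative to all genes, or -1.40 at the bounds; camera adjusted p = 0.452). Among 4 sex-linked genes, 2 fell and 0 rose, also when adjusted over the list alone (median -0.28 relative to all genes; camera adjusted p = 0.299). Beside Xist, Kdm5d on the Y chromosome fell by 0.84 on the log2 scale (adjusted p = 0.0364), a call that was lost after quantile normalization and after centring on the median or the percentile 75 (adjusted p = 0.0944, 0.0854 and 0.0950), with replicate number as a block (0.0648), without the filter (0.109), at a threshold of 0.01, and without fetal liver replicate 2 or 3 or old replicate 2 (adjusted p = 0.126, 0.135 and 0.105). Eif2s3y, also on the Y, had 11.18 in fetal liver and 11.12 in old HSCs.

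Of 18 glycolysis genes, 8 rose and 2, the glucose transporter Slc2a1 and the kinase Pdk1, fell, also when adjusted over the list alone (median 0.74 relative to all genes; camera adjusted p = 0.0365; adjusted p = 0.550 with an estimated correlation). The phosphofructokinase Pfkp was 3.56-fold, hexokinase Hk1 2.59-fold and pyruvate kinase Pkm 2.33-fold higher. Slc2a1 changed by -1.49, but by -0.76 without possibly cross-hybridizing probe sets, where it was not called (adjusted p = 0.123). The call of this list was lost without fetal liver replicate 3 (adjusted p = 0.0560) and without old replicate 3 (adjusted p = 0.106), without the filter (0.0612), with the mean of probe sets (0.0653) and without possibly cross-hybridizing probe sets (0.372, with 3 risen and 1 fallen of 8), and that of Hk1 without fetal liver replicate 3 (adjusted p = 0.0537) and without the filter (0.0758). Among 38 genes of oxidative phosphorylation, 8 fell (6 adjusted over the list alone) and 1, Ndufa2, rose, and after median centring 3 fell and 3 rose (median -0.24, against -0.24 for all genes; camera adjusted p = 0.765). Leaving out 1 array gave from 0 risen and 3 fallen (without fetal liver replicate 1) to 10 risen and 14 fallen (without old replicate 3), and fewer fell also without fetal liver replicate 2 (5), fetal liver replicate 3 (3) and old replicate 2 (4). Cytochrome c (Cycs) was 2.29-fold and Ndufs1 1.88-fold lower. Transcription factors of HSCs rose in 5 of 21 cases (Hoxb4, Hoxb5, Gata2, Etv6 and Gfi1b) and fell in 4 (Hoxa9, Zfx, Mecom and Hlf), also when adjusted over the list alone. Their median of -0.15, mean of -0.01 and upward test differed in sign (camera adjusted p = 0.493), and after median centring 7 rose and 2 fell, with a median of 0.05. Without old replicate 3, 6 rose and 10 fell, and without fetal liver replicate 3, 4 rose and 2 fell. The call of Hoxb5 was lost without the filter (adjusted p = 0.0502). With the mean of each gene's probe sets that list passed as higher, at 0.47 (adjusted p = 0.0219).

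The control probe sets for RNA integrity differed between the groups. The 3′ minus 5′ signal of actin was 2.73 ± 0.08 in fetal liver and 1.82 ± 0.10 in old HSCs (SD, n = 3; exact permutation p = 0.1), and that of Gapdh 2.99 ± 0.21 and 3.40 ± 0.18 (exact permutation p = 0.1), the smallest p this design allows. The 2 indices pointed in opposite directions. The median SD of a gene was 0.148 among fetal liver arrays and 0.344 among old arrays.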

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

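No alternative here was chosen after the result was seen. Of 177 named genes followed, 132 were called; 8 lost their call when some array was left out and 0 reversed, while in the other settings 15 lost it and 2 reversed. The whole-series table gave the same 5166 genes. Leaving out an array gave 3804 to 7025 genes, 7355 to 13772 probe sets, 14 to 15 lists and 4 to 5 families; 7025 and 13772 came without old replicate 3. Without a filter 4372 genes were called, of which 3999 were shared, at a filter of 6 4551, after quantile normalization 5029, after median centring 5049 and with probe sets without possible cross-hybridization 4371. The deviations of same-numbered arrays correlated at -0.01, 0.12 and 0.02, and not every array correlated best with its own number. Deviations of 3 arrays from their own mean are tied to each other, so these values cannot exclude a shared day or batch. A replicate block gave 5111 genes, 4872 of them shared, 9858 probe sets and 15 lists. An adjusted p of 0.01 kept 6602 probe sets, and an absolute log2 change of at least 1 kept 3358 genes, both by construction. An estimated correlation left 2 lists and 0 families past the threshold, with 2 families at an unadjusted p under 0.05. Fry, which compares no list with other genes, called 23 lists and 72 families. The families past the threshold were 1 of 94 without possibly cross-hybridizing probe sets, where fewer genes were tested, and 2 with the mean of probe sets, where the cause was not tested. Without possibly cross-hybridizing probe sets Hspa8 was 1.87 and Rbbp4 0.92; with the mean of probe sets Zbtb38 was 0.996, Hsp90b1 0.97, Klf6 0.93, and Nolc1 0.13. These 6 genes were negative with the brightest probe set, and other probe sets of each were higher in old HSCs. The HSC transcription factor median was 0.47 with the mean of probe sets, and the cause was not tested. Slc2a1 and Hspa1b lost their call without possibly cross-hybridizing probe sets (adjusted p = 0.123 and 0.0834). The robust option was not run for lists and families, as camera has none. Signal over the floor limits what was seen: 261 called genes lay near the floor on all fetal liver arrays and 277 on all old arrays, so their folds are bounds.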

Other observations

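The tests on liver genes were chosen only after the result was seen, and the second gene lists were drawn up after the first lists had been tested.

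Signalling genes of the transforming growth factor beta and bone morphogenetic protein pathways went both ways, with 7 of 22 risen and 6 fallen, also when adjusted over the list alone (median 0.55 relative to all genes; camera adjusted p = 0.163). The ligand gene Bmp4 was at least 9.12-fold higher in old HSCs, its receptor gene Bmpr1a at least 15.4-fold higher (1 of 3 fetal liver arrays above 4), and Ltbp3, which stores latent ligand in the matrix, 22.5-fold higher. Id3, a target of the pathway, was at least 2.46-fold lower. Among p53 targets 3 of 11 rose and 5 fell, also when adjusted over the list alone. The kinase gene Plk2 was at least 19-fold and Sesn2 3.50-fold higher, the third being Cdkn1a, and Zmat3 was 2.71-fold lower. The p53 median was -0.47, its mean 0.10 and its test downward (camera adjusted p = 0.948), and without fetal liver replicate 2, 2 rose and 3 fell.

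Chaperone genes were lower in 8 of 17 cases (9 adjusted over the list alone) and higher in 2, Hspa1b (2.83-fold) and Calr (camera adjusted p = 0.299; median -0.14 relative to all genes). Without any 1 of the fetal liver arrays, 5 of the 17 fell, and without possibly cross-hybridizing probe sets 1 rose and 2 fell of 11. Hspa1b lost its call in the latter setting (1.12, adjusted p = 0.0834). Hspd1 and Hsph1 were 2.76-fold and 2.43-fold lower. Hsp90b1 fell by 0.88 with its brightest probe set and was 0.97 higher with the mean of its probe sets, which disagreed. Ribosome biogenesis genes rose in 3 of 24 cases (Rrp9, Nop58 and Nop2) and fell in 6, with Wdr12 2.11-fold lower, the same counts as when adjusted over the list alone (median -0.01 relative to all genes; camera adjusted p = 0.742). After median centring 5 rose and 5 fell, and without old replicate 3, 5 rose and 15 fell. Cholesterol synthesis genes rose in 4 of 16 cases and fell in 5, also when adjusted over the list alone, with Insig1 2.55-fold (adjusted p = 0.0783 without fetal liver replicate 2 and 0.103 without the filter) and Dhcr7 2.06-fold higher and Cyp51 2.31-fold lower. Their median was -0.07 and their mean -0.05 with an upward camera test (adjusted p = 0.791), and the median was 0.13 after median centring.

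Most red cell and neutrophil markers and 4 of 5 tested liver markers were higher in fetal liver HSCs (Car1, Aqp1, Prtn3, Csf3r, C1qb, Padi4 and Krt18 were higher in old HSCs), and precursors carried over in the fetal liver sort are a candidate explanation. In a second erythroid list, 25 of 27 tested genes fell (92.6%, exact binomial 95% interval 75.7% to 99.1%, median -2.64). In a second granulocyte list 15 of 19 fell (78.9%, 54.4% to 93.9%, median -3.30), against 3267 of all 9907 genes. Carry-over of either cell type would give this, and so would transcription by the fetal HSCs. All 27 and all 19 exceeded 4 on every fetal liver array, and 20 of the 27 and 7 of the 19 on all old arrays. The others passed the filter only through fetal liver, so their fall was nearly set in advance. The intervals treat genes as independent, which they are not. For hepatoblasts, 6 of 42 liver genes (14.3%, 5.43% to 28.5%) exceeded 4 on all 3 fetal liver arrays, 4 of them falling in old HSCs, among them Afp (12.33), Alb (9.25) and Ttr (8.53), while Apoe, the only tested gene of the second liver list, rose by 1.30, so this source remains open. Both gates removed lineage-positive cells, but the fetal liver gate kept Mac1, which granulocytes and monocytes also carry. Itgam, the gene of Mac1, did not exceed 4 on all 3 fetal liver arrays and was not tested. Transcription of these genes by the fetal HSCs themselves, tied to tissue, age, gate or sex composition, was not tested and stays open.

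Immediate early genes were higher in old HSCs in both the first list and a second list, in which 10 of 16 rose and 1 fell (median 1.25). A rise set by a lone old array is argued against, since at least 13 members of the first list were called as risen without each old array in turn, against 13 with all arrays. Heat or proteotoxic stress during isolation could raise such genes. Of 10 tested stress chaperone genes, 2 rose (20%, exact binomial 95% interval 2.52% to 55.6%) and 5 fell (median -0.46), an interval too wide to exclude it. The risen genes were Bag3, by 2.32 on the log2 scale, and Hspa1b, 2.83-fold. The list was not divided into inducible and constitutive members, so its share of risen genes cannot decide the question. The time and handling of the isolation, which the labels do not give, may also have differed between marrow and fetal liver, and this was not tested. Age, tissue, gate and sex composition stay open as biological sources, also untested.

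More genes fell than rose in old HSCs, and array scaling is a candidate explanation for part of that excess. After centring each array on its median, the share of called genes that rose was 46.7%, against 36.8% before. A true excess of lower transcripts in old HSCs would be removed by the same centring, so it stays open and was not tested.

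The real split of the 6 arrays gave 5166 called genes and 10179 called probe sets, and the highest of the other splits gave 0 in each case. It was the only 1 of 10 splits to give as many, both for genes and for probe sets, and 10 splits are too few for a share under 0.05. Each of the other splits mixed both groups, so the difference between the groups entered its spread and nearly fixed the low counts in advance. The contrast therefore says little about chance. At an unadjusted p under 0.05 the real split had 5793 genes.

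Xist and Y-linked transcripts were both present on the fetal liver arrays, with Xist at 12.62 ± 0.23 and Eif2s3y above 4 on all of them. Fetal liver samples holding female and male cells would give this. On the old arrays, from male mice, Xist was at 3.49 ± 0.28, while Eif2s3y was at a similar level in both groups. By Xist, sex composition may therefore have differed between the groups along with tissue, age and gate. The Y-linked genes did not show this, since neither Eif2s3y nor Kdm5d was lower in fetal liver than on the male old arrays. Embryonic globins varied among fetal liver arrays, Hbb-y from 4.38 to 9.07 and Hbb-bh1 from 2.24 to 8.17, with Hbb-y highest and Hbb-bh1 lowest on replicate 2. These values came from possibly cross-hybridizing probe sets. Another probe set of Hbb-y lay at the floor on every array, and another of Hbb-bh1 had 3.45, 2.24 and 2.25 in fetal liver. Alpha-globin varied among old arrays, at 5.97, 8.14 and 2.80 on the shared probe set with the highest mean over the 6 arrays.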
